A study of Mus musculus with 58 samples.

How the data were processed

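The series holds 58 samples of mouse adipocytes, of which 22 are mRNA libraries and 36 are chromatin immunoprecipitation samples of histone marks (14 for H3K27ac and 22 for H3K4me1). The processed file at hand held only the mRNA libraries, so the chromatin samples were left out. Per the labels' protocols, adipose tissue was homogenised, tagged ribosomes were pulled down with an antibody against GFP, ribosomal RNA was depleted with Ribo-Zero, and libraries were made with Nextera XT and sequenced on a HiSeq2500. The sample descriptions call each library a biological replicate and do not say which animals were shared between tissues.

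The deposited table holds 1 row for each of 11603 UCSC known-gene identifiers, paired with 11544 distinct symbols, and 117 rows carry a symbol that occurs more than once. The values were deposited as log2 CPM (read counts scaled to a common nominal total), a unit read from the table's name and from the values, which ran from -7.21 to 15.78. Per the submitters' processing notes, HISAT2, Picard, featureCounts and edgeR were used with the mouse build mm10, with no versions, roles or order given. The counting annotation and the use of strand are not stated, so reads of overlapping or near-identical genes could not be told apart. The antilogs of the deposited values summed to between 0.859 and 1.10 times the nominal total of a CPM scale. The depth of each library is unknown, no whole read counts could be recovered from the deposited values, and no interval from counting error could be given. Values at or below -5 log2 units were treated as a floor, and how the submitters handled genes with no reads is not stated.

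The deposited values carry the mark of a removed batch effect. Rows at the floor in every library of a depot (9 in brown fat and 2 in inguinal fat) took 2 slightly different values, which parted the libraries into 10 of batch 1 and 12 of batch 2. Fitting group and batch to every row gave batch coefficients of at most 0.005 log2 units, against up to 1.90 when the partitions of the depots were joined the other way. Batch 1 held 2 cold brown, 2 warm brown, 2 cold beige, 1 warm beige and 3 warm white libraries, and batch 2 held the rest. The labels name no batch, so this division is read from the values alone. Each comparison was repeated within each batch, and genes called there in the opposite direction to the fit of all 22 libraries were counted. That fit includes the libraries of the batch, so agreement is partly built in, and the batches were not compared with each other.

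All 22 libraries entered 1 limma-trend fit (limma 3.58.1, R 4.3.3) with a mean for each of 5 groups and no covariate, on the deposited log2 values. The planned test was on log2 values of CPM with 1 added. The plan also named the deposited values as the choice if the table already held logarithms, and adding 1 CPM became an alternative. The fit left 17 residual degrees of freedom, against 16 with a batch term, so the batch effect removed before deposit is not counted. The variance prior followed the mean, and p-values were two-sided and adjusted by Benjamini and Hochberg over 11603 rows, with a threshold of 0.05. The filter asked for at least 1 CPM in at least 3 libraries, and every deposited row passed it. Each gene's log2 fold change is given with limma's standard error, and group levels are means with the standard deviation. Where every library of a group lay at or below the floor, no fold change is given for a comparison of groups, and a difference of warming effects is marked as resting on the floor.

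There were 34 gene lists, written from general knowledge before the data were examined, which cover adipocyte identity, metabolism, signalling and markers of other cell types. Of these, 30 had at least 4 measured genes and were tested in each of 8 comparisons with limma's camera, with the correlation between genes estimated for each list and adjustment over the lists within a comparison. Members past the threshold were counted over all genes and also adjusted over the list alone. Of the 240 list tests, 9 passed with an estimated correlation, and 100 passed with camera's preset correlation of 0.01. All 9 also passed with the preset one: the thermogenic list in every comparison except brown warming and cold beige against cold brown, and the reported beige markers in both comparisons of beige with brown and in warm brown against warm white.

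A position between cold beige (0%) and warm white (100%) was computed for each library, as the projection of its values on the difference between these group means over the genes called between them. Libraries of the end groups were placed on an axis built without them. Warm beige was compared with each end group by an exact two-sided permutation test.

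The named genes were chosen by a rule set before the data were examined. It took Ucp1, Cidea, Ppargc1a, Elovl3, Dio2, Adipoq and Lep in every comparison. It added the 8 genes with the largest log2 fold change in each direction among those past the threshold with a mean of at least 10 CPM in the higher group and no overlap between the groups (for the difference of warming effects, past the threshold with a mean of at least 10 CPM in any of the 4 groups), without Y-linked genes. It also took up to 4 members with the smallest adjusted p of each list described. In the last 4 comparisons fewer were named, and in the first 4 the text leaves out some genes that the rule gives. Which lists to describe was chosen after their values were seen. Coordinates come from a RefSeq gene table of GRCm38.p6, the build family of mm10, in which 10933 of the symbols had an entry and a further 272 matched an older name.

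Library numbers in the sample descriptions were checked for pairing. Over the 8868 genes with a mean above 3 log2 CPM, deviations from the group means of same-numbered libraries correlated at 0.127 to 0.327 in the 4 pairs of cold beige and cold brown, and at 0.176 to 0.33 in the 3 pairs of warm beige and warm brown. Every pair passed 0.1, so these numbers were taken to pair the libraries, as a reading of the data and not of a label. Over all 11603 genes the lowest pair lay at 0.071 in the cold and at 0.065 in the warm, so the pairing depends on which genes are used. A block of temperature and library number together was therefore added as an alternative after the data were seen. In no other comparison did every pair pass.

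The fit was tested on simulated data with the real spread, in which 200 of 11603 genes were changed. For beige warming it called 40% of genes changed by 0.5 log2 units, 72% of those changed by 1, 88% at 2 and 92% at 3, with 9 unchanged genes called. For brown warming the shares were 54%, 92%, 96% and 100%, with 10 unchanged genes called, and no call had the wrong sign. Genes were drawn independently and far fewer were changed than the 8453 called for real beige warming, so these shares need not carry over. Camera called a simulated changed list of 30 genes and left an unchanged one uncalled. That does not show how camera performs on lists whose genes are correlated. Simulated positions of 0%, 60% and 100% were recovered as 1.29%, 60.0% and 98.8%.

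Alternatives to the added constant, filter, groups in the fit, variance prior, library weights, scaling, replicate block, batch and list test were run, as was leaving out each library of the compared groups. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and drew the figures.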

Results

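Ribosome-bound mRNA of brown, beige and white adipocytes was measured in 22 libraries of C57BL/6J mice. NuTRAP mice carry a GFP tag on the ribosomes of cells that express a chosen Cre, and TRAP pulls down those ribosomes with their mRNA. The labels name an Ucp1-NuTRAP and an Adipoq-NuTRAP line but do not give the line of each library. Brown libraries came from interscapular brown fat of mice kept at 4 °C for 1 week (cold brown, n = 5), or then moved to 30 °C for 4 weeks (warm brown, n = 5). Beige libraries came from inguinal white fat after the same treatments (cold beige, n = 4; warm beige, n = 3). Warm white libraries came from inguinal fat of mice born and kept at 30 °C (n = 5). The depth of the libraries is unknown, and the antilogs of their values summed to between 0.859 and 1.10 times the nominal total of a CPM scale.

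The series title contrasts beige with brown cells in how far warming changes their identity, and 7 genes were fixed for every comparison. In GRCm38.p6 these were Ucp1 (uc009mjx.2, chromosome 8, 83290348 to 83298456), Cidea (uc012beh.1, chromosome 18, 67343564 to 67367794), Ppargc1a (uc008xkc.2, chromosome 5, 51454249 to 52115853) and Elovl3 (uc008hsk.1, chromosome 19, 46131897 to 46135694). The others were Dio2 (uc007okf.1, chromosome 12, 90724552 to 90739038), Adipoq (uc007ytk.1, chromosome 16, 23146536 to 23157968) and Lep (uc009bcv.1, chromosome 6, 29060221 to 29073876).

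**Figure D1:**
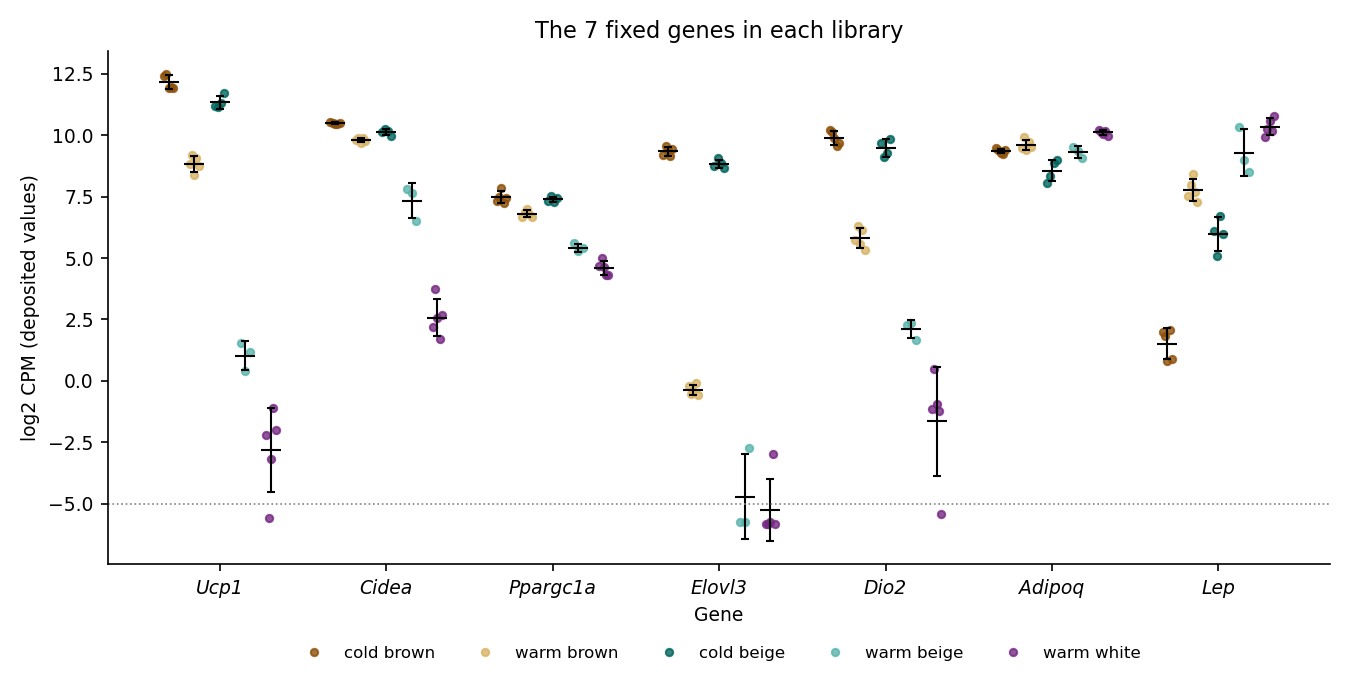
Deposited log2 CPM (y axis) of the 7 fixed genes (x axis) in each library, coloured by group; horizontal bars are group means, vertical bars standard deviations, and the dotted line is the floor of -5. Ucp1 averaged 12.15 in cold brown, 8.84 in warm brown, 11.34 in cold beige, 1.03 in warm beige and -2.82 in warm white libraries.

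The comparison of warm with cold beige libraries asks how the mRNA of beige cells differed after rewarming (n = 3 warm and 4 cold). Ucp1, which uncouples respiration from ATP synthesis, fell by 10.31 ± 0.60 log2 units (SE; adjusted p = 7.13e-13), from 11.34 ± 0.25 log2 CPM (SD) to 1.03 ± 0.59. Elovl3, a fatty acid elongase induced by cold, fell by 13.56 ± 0.60 to values around the floor, and by the smaller measure with 1 CPM added it changed by -8.75. Dio2, which makes active thyroid hormone, fell by 7.38 ± 0.75, Cidea, a lipid droplet protein, fell by 2.81 ± 0.30, and Ppargc1a, a coactivator of mitochondrial genes, fell by 1.96 ± 0.15. Lep, which encodes leptin, rose by 3.31 ± 0.40, and Adipoq, which encodes adiponectin, rose by 0.76 ± 0.17 (adjusted p = 0.000331).

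The thermogenic list fell in beige cells on warming (camera, adjusted p = 0.00189), with a median log2 fold change of -3.48. Of its 29 measured members 26 fell and 1 rose, with the same counts adjusted over the list alone. Gk, the glycerol kinase, fell by 5.82 ± 0.13, Clstn3 fell by 5.02 ± 0.13, Cox8b, a subunit of cytochrome oxidase, fell by 4.05 ± 0.13, and the mitochondrial protein gene Letmd1 fell by 4.01 ± 0.08. Of 76 measured genes of the nuclear-encoded respiratory chain, 69 fell and 1 rose (69 and 2 adjusted over the list alone), with a median of -1.53 and adjusted p = 0.244 with an estimated correlation. Among them cytochrome c, Cycs, fell by 3.34 ± 0.12 and the complex I subunit Ndufa8 fell by 2.24 ± 0.09.

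Of 31 genes of fatty acid oxidation 30 fell and 1 rose in beige cells on warming (also adjusted over the list alone; adjusted p = 0.0982 with an estimated correlation), and Slc25a20, the carnitine-acylcarnitine carrier, fell by 3.52 ± 0.10. The electron transfer enzyme Etfdh fell by 3.73 ± 0.13, and the short-chain dehydrogenase Acads fell by 2.11 ± 0.07. Of 23 lipogenic genes 21 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.219 with an estimated correlation). The elongase Elovl6 fell by 4.69 ± 0.12, the acyltransferase Agpat2 fell by 4.50 ± 0.20 and glycerol phosphate dehydrogenase, Gpd1, fell by 3.23 ± 0.15. Of 23 genes of glycolysis and glucose uptake 20 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.121 with an estimated correlation), with the glycolytic enzyme genes Eno1 at -3.19 ± 0.10 and Pgam1 at -2.65 ± 0.10.

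Interferon response genes and white adipocyte markers included members that rose in beige cells. Of 28 measured interferon response genes 24 rose and 1 fell (25 and 1 adjusted over the list alone; adjusted p = 0.352 with an estimated correlation), with Bst2 at 2.60 ± 0.17 and the transcription factor gene Irf9 at 1.42 ± 0.15, while Ifi27 fell by 1.29 ± 0.11. Of 17 white adipocyte markers 8 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.397 with an estimated correlation). The imprinted gene Nnat rose by 5.85 ± 0.36, Ccdc80 rose by 3.16 ± 0.20, and Hcar1, the lactate receptor, rose by 2.49 ± 0.27.

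Of 18 endothelial markers 13 rose and 0 fell in beige cells on warming (also adjusted over the list alone; adjusted p = 0.683 with an estimated correlation), with the clotting factor carrier Vwf at 3.25 ± 0.66, the receptor Tie1 at 1.74 ± 0.40 and the tight junction gene Cldn5 at 1.90 ± 0.44. Of 19 fibroblast and preadipocyte markers 12 rose and 0 fell (also adjusted over the list alone; adjusted p = 0.49 with an estimated correlation), with Gsn at 2.63 ± 0.19 and the collagen gene Col1a2 at 2.68 ± 0.29. Of 16 skeletal muscle markers 13 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.686 with an estimated correlation). The members that fell were Mb, myoglobin, at -4.24 ± 0.43 and the myosin light chain gene Myl1 at -1.64 ± 0.28. Pre-ribosomal RNA, Rn45s, made up 4.32% to 5.72% of the summed values in warm beige libraries and 0.436% to 1.15% in cold beige libraries.

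The largest increases among genes within the limits of the naming rule included muscle genes and genes of other kinds. Pvalb, parvalbumin, rose by 7.34 ± 1.74 (3.11 with 1 CPM added), Myh4, a fast myosin, rose by 6.43 ± 1.66 (4.25) and the sarcomere gene Tcap rose by 5.90 ± 1.68 (2.86). Others were Nnat, the secreted chaperone gene Clu at 5.61 ± 0.38, Ier5 at 5.17 ± 0.56 and the membrane protein gene Emp1 at 5.14 ± 0.41. The largest decreases within these limits besides Elovl3 and Ucp1 included Lgr6, an R-spondin receptor, at -11.06 ± 0.81 (-6.73 with 1 CPM added), Kng2, a kininogen, at -9.08 ± 0.85 (-6.22) and 2310069B03Rik at -9.31 ± 0.87 (-4.74). A530050N04Rik at 5.12 ± 0.21, the kinase gene Sgk2 at 4.24 ± 0.21 and 9030619P08Rik at 3.73 ± 0.61 log2 CPM in cold beige were at the floor in every warm beige library.

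Limma called 8453 of 11603 genes between warm and cold beige, of which 4177 rose and 4276 fell, and 3885 of these by at least 2-fold. Within batch 2 (4 libraries) 7929 genes were called, with 0 in the opposite direction to the fit of all libraries. Within batch 1 (3 libraries, 1 of them warm beige) the estimates of 99.04% of the genes called in that fit had the same sign. The share of increases among the calls was 49.4%, and 60.8% with library totals computed without the 20 most abundant genes.

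**Figure D2:**
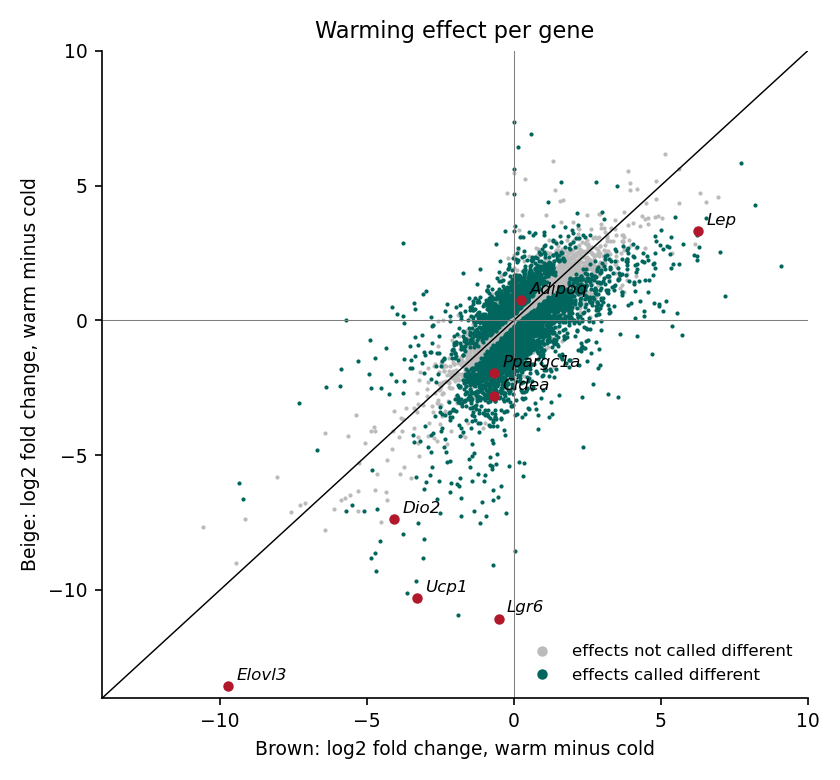
Log2 fold change of each gene on warming in brown (x axis) and beige (y axis) cells, with genes whose effects were called different in green, the others in grey, named genes in red and the line of equal effects in black. Lgr6 lay at -0.52 in brown and -11.06 in beige, and Lep at 6.26 and 3.31.

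The comparison of warm with cold brown libraries asks the same of interscapular brown fat (n = 5 each). Ucp1 fell by 3.31 ± 0.49 log2 units (adjusted p = 3.13e-06), from 12.15 ± 0.28 to 8.84 ± 0.32 log2 CPM, and Elovl3 fell by 9.72 ± 0.49 to -0.37 ± 0.21 log2 CPM. Dio2 fell by 4.08 ± 0.62, Ppargc1a fell by 0.68 ± 0.12 and Cidea fell by 0.69 ± 0.25 (adjusted p = 0.0174, and 0.201 after quantile normalization). Lep rose by 6.26 ± 0.33, the largest change of the fixed genes upward, and Adipoq, at 0.25 ± 0.14, did not pass the test (adjusted p = 0.111), but passed after quantile normalization (0.00377), with libraries set to a common total (0.0172), with library totals computed without the 20 most abundant genes (0.0227), with library weights (0.0329) and when only these groups were fitted (0.0226).

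In brown cells on warming no list passed camera with an estimated correlation. Of the 29 thermogenic members 18 fell and 3 rose (18 and 4 adjusted over the list alone; adjusted p = 0.224 with an estimated correlation), with a median of -0.69. Gk fell by 3.33 ± 0.11, Ffar4, a fatty acid receptor, fell by 3.76 ± 0.17, and Letmd1 fell by 1.44 ± 0.07. In the respiratory chain 40 of 76 fell and 5 rose (38 and 5 adjusted over the list alone; adjusted p = 0.58 with an estimated correlation), with a median of -0.26 and Ndufa9 at -1.03 ± 0.09 and Ndufs3 at -0.99 ± 0.09. For fatty acid oxidation 22 of 31 fell and 5 rose (also adjusted over the list alone; adjusted p = 0.327 with an estimated correlation), with Acsl5 at -2.82 ± 0.09, Cpt2 at -1.73 ± 0.09 and Ehhadh at -3.31 ± 0.19.

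Of 23 lipogenic genes 19 fell and 0 rose in brown cells (also adjusted over the list alone; adjusted p = 0.327 with an estimated correlation), with fatty acid synthase, Fasn, at -3.27 ± 0.21, Elovl6 at -2.93 ± 0.10 and Agpat2 at -3.38 ± 0.16. Of 22 genes of cholesterol synthesis and uptake 18 fell and 0 rose (also adjusted over the list alone; adjusted p = 0.327 with an estimated correlation), with the farnesyl diphosphate synthase Fdps at -2.52 ± 0.17 and the desaturase Sc5d at -2.0 ± 0.14. Of 28 interferon response genes 27 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.327 with an estimated correlation), with a median of 2.33 and the GTPase genes Gbp2 at 4.35 ± 0.26 and Gbp3 at 2.40 ± 0.13, and Bst2 at 2.52 ± 0.14. Of 19 fibroblast markers 16 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.572 with an estimated correlation), with Gsn at 3.46 ± 0.16 and Gas1 at 1.99 ± 0.16. White markers counted 9 of 17 rising and 1 falling, also adjusted over the list alone (adjusted p = 0.507 with an estimated correlation), with Hcar1 at 4.80 ± 0.22. Of the endothelial markers 6 of 18 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.784 with an estimated correlation). Their median relative to the white mean stood at 1.22 and 1.04 in cold brown 1 and 5. It stood at -0.59 to -0.29 in the other cold brown libraries. Of the macrophage markers 6 of 12 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.584 with an estimated correlation). The red blood cell genes Alas2 (-1.19 ± 0.30, and -0.79 with 1 CPM added), Hbb-bs (-1.16 ± 0.31) and Hba-a2 (-1.67 ± 0.64) fell. Hba-a2 (adjusted p = 0.0234) lost its call without cold brown 1 (0.0626). Rn45s made up 0.11% to 0.597% of the summed values in warm brown and 0.058% to 0.099% in cold brown libraries.

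The largest increases in brown cells within the limits of the naming rule besides Lep included Cdsn, corneodesmosin, at 9.10 ± 0.43 (5.18 with 1 CPM added), Nnat at 7.74 ± 0.30, the caspase gene Casp12 at 7.03 ± 0.33 (4.14) and the Wnt inhibitor gene Apcdd1 at 6.52 ± 0.31. They also held the adenylate cyclase gene Adcy5 at 6.31 ± 0.18, the matrix gene Fras1 at 6.25 ± 0.72 and the potassium channel gene Kcna2 at 6.25 ± 0.33. The largest decreases within these limits besides Elovl3 included the lipid transporter gene Mfsd2a at -10.57 ± 0.77 (-5.09 with 1 CPM added), Cpne5 at -9.46 ± 0.56 (-5.24) and the phosphatase gene Dusp15 at -9.22 ± 0.58 (-5.12). Sult5a1, a sulfotransferase, fell by 7.31 ± 0.80 (4.26) and Bmp8b, a secreted factor of thermogenic fat, fell by 7.27 ± 0.83. A further transcript row of Cpne5 and the phospholipase gene Pla2g2e, at 3.37 ± 0.61 log2 CPM in cold brown, were at the floor in every warm brown library.

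Limma called 8274 of 11603 genes between warm and cold brown, of which 4777 rose and 3497 fell, and 2867 of these by at least 2-fold. The share of increases among the calls was 57.7%, and it was 49.8% after quantile normalization, 49.95% after median-of-ratios scaling and 67.6% with libraries set to a common total. Within batch 1 (4 libraries) 5050 were called and within batch 2 (6 libraries) 7851. Within the batches 0 were called in the opposite direction to the fit of all libraries.

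The difference between these effects asks whether beige and brown cells responded unequally to warming. Ucp1 fell by 7.00 ± 0.77 log2 units more in beige than in brown cells (adjusted p = 1.59e-07), a difference of -7.00, Dio2 differed by -3.30 ± 0.98, Cidea by -2.12 ± 0.39 and Ppargc1a by -1.29 ± 0.19. Lep differed by -2.95 ± 0.52, since it rose more in brown cells. Elovl3 differed by -3.84 ± 0.77, but by -0.23 with 1 CPM added (adjusted p = 0.204) and by 0.32 with 5 CPM added, so its sign rested on values at the floor. Adipoq differed by 0.51 ± 0.22 (adjusted p = 0.0572), and it passed without warm brown 2, cold beige 3, cold beige 4 or warm beige 3 (adjusted p of 0.0112 to 0.0291), after median-of-ratios scaling (0.0138), after quantile normalization (0.0292) and with library totals computed without the 20 most abundant genes (0.0314).

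The thermogenic list fell more in beige than in brown cells (camera, adjusted p = 0.00342), with 24 of 29 members called lower and 1 higher (26 and 1 adjusted over the list alone) and a median of -2.56. With temperature and library number together as a block the list's adjusted p was 0.355. Among its members Cox8b differed by -3.72 ± 0.17, Clstn3 by -3.59 ± 0.16, the receptor gene Ppara by -3.59 ± 0.22 and Letmd1 by -2.56 ± 0.10. In the respiratory chain 68 of 76 differed downward and 1 upward (also adjusted over the list alone; adjusted p = 0.419 with an estimated correlation), with Cycs at -2.47 ± 0.15 and Ndufa8 at -1.85 ± 0.11. In fatty acid oxidation 26 of 31 differed downward and 1 upward (27 and 1 adjusted over the list alone; adjusted p = 0.261 with an estimated correlation), with Acaa2, the mitochondrial thiolase, at -2.92 ± 0.17 and Slc25a20 at -2.52 ± 0.13. For glycolysis and glucose uptake the counts were 14 of 23 downward and 0 upward (14 and 1 adjusted over the list alone; adjusted p = 0.419 with an estimated correlation).

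The largest positive differences within the limits of the naming rule included muscle genes. Pvalb differed by 7.34 ± 2.26 (3.11 with 1 CPM added), the muscle actin gene Acta1 by 6.64 ± 1.26 (3.22), Myh4 by 6.29 ± 2.16 and the troponin gene Tnni2 by 5.62 ± 2.21 (2.59), beside A930016O22Rik at 6.32 ± 2.30 (3.5). Pvalb lost its call with 5 CPM added (adjusted p = 0.0513), and the calls of 3 others depended on single libraries. Tnni2 (adjusted p = 0.0408) lost its call without any of cold brown 3, 4 and 5, warm brown 1 and 2, cold beige 1, 2 and 3, and warm beige 1 and 2 (0.0604 to 0.116), with a filter of 5 CPM (0.0578) and with a block of replicate number (0.0599) or library number (0.0727). A930016O22Rik (adjusted p = 0.0277) lost it without any of warm brown 2, cold beige 1, 2 and 3, and warm beige 1 and 2 (0.0502 to 0.0805) and with a block of library number (0.0504), and Myh4 (adjusted p = 0.0202) lost it without warm beige 1 or 2 (0.0635 to 0.0659). Of the skeletal muscle list 4 of 16 differed upward and 1 downward (3 and 0 adjusted over the list alone; adjusted p = 0.942 with an estimated correlation). Other positive differences were Sult5a1 at 4.23 ± 1.25 (2.31 with 1 CPM added) and the homeodomain gene Hopx at 4.08 ± 0.50.

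The largest negative differences within the limits of the naming rule besides Ucp1 included Lgr6 at -10.54 ± 1.05 (-6.22 with 1 CPM added), Arhgdig at -8.59 ± 0.69 (-4.0), Kng2 at -8.37 ± 1.11 (-5.51), Cdsn at -7.07 ± 0.67 (-3.32) and the cilium gene Cfap54 at -7.05 ± 1.04 (-3.89). A530050N04Rik and Sgk2 were also called, with warm beige libraries at the floor and warm brown libraries at 5.44 ± 0.15 and 1.85 ± 0.28 log2 CPM. Adding 5 CPM turned the sign of Sgk2 to 0.30.

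Limma called 5477 of 11603 genes for the difference of warming effects, of which 1712 were higher and 3765 lower. Of these, 2478 had estimates of the same sign in both cell types and a larger one in beige, 1132 a larger one in brown, and 1867 had estimates of opposite sign, whether or not each estimate passed. Across genes the warming effects correlated at r = 0.707 with a covariance of 1.09, although genes are not independent replicates. The cell types shared 3112 genes that rose (1720 if the lists were independent) and 2711 that fell (1289), against 196 and 458 with opposite calls (1259 and 1760). No library was shared between these comparisons, but animals may have been. Within batch 2 (10 libraries) 4829 were called, with 0 in the opposite direction to the fit of all libraries. Within batch 1 (7 libraries, 1 of them warm beige) the estimates of 99.2% of the genes called in that fit had the same sign. The share of positive differences among the calls was 31.3%, and it was 49.7% after quantile normalization and 46.0% after median-of-ratios scaling.

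The comparison of warm beige with warm white libraries asks how close rewarmed beige cells came to white cells of the same depot (n = 3 and 5). Lifelong temperature differed too, and the mouse line, and with it the labelled cells, may have differed. Cidea was higher in warm beige by 4.76 ± 0.29 log2 units (adjusted p = 3.39e-11), Ucp1 by 3.84 ± 0.57 (1.35 with 1 CPM added), Dio2 by 3.75 ± 0.72 (1.81) and Ppargc1a by 0.83 ± 0.14. Elovl3 differed by 0.52 ± 0.57 and did not pass (adjusted p = 0.498), and its sign turned to -0.48 without warm beige 3. Adipoq was lower by 0.80 ± 0.16. Lep was lower by 1.06 ± 0.38 (adjusted p = 0.0315), a call that was lost without warm beige 2 or 3 or warm white 3 or 5 (0.0577 to 0.217), with library weights (0.074) and with a block of library number (0.0599).

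The thermogenic list was higher in warm beige than in warm white (camera, adjusted p = 0.00135), with 20 of 29 members higher and 2 lower, also adjusted over the list alone, and a median of 0.96. Cox8b was higher by 2.62 ± 0.13, the carnitine transferase gene Cpt1b by 3.96 ± 0.22, the receptor gene Ntrk3 by 3.74 ± 0.25 and the respiratory subunit gene Cox7a1 by 4.90 ± 0.62 (2.36 with 1 CPM added). In the respiratory chain 52 of 76 were higher and 1 lower (55 and 1 adjusted over the list alone; adjusted p = 0.315 with an estimated correlation), with a median of 0.42. In fatty acid oxidation 18 of 31 were higher and 1 lower (19 and 1 adjusted over the list alone; adjusted p = 0.209 with an estimated correlation), with the kinase gene Pdk4 at 3.40 ± 0.13 and Acaa2 at 1.66 ± 0.13. White markers were lower in 11 of 17 and higher in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.209 with an estimated correlation), with Ccdc80 at -1.42 ± 0.19 and Enpp2, which makes lysophosphatidic acid, at -0.91 ± 0.09. Cholesterol genes were lower in 13 of 22 and higher in 0, also adjusted over the list alone (adjusted p = 0.342 with an estimated correlation), with the sterol isomerase gene Ebp at -0.57 ± 0.09.

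All 18 measured endothelial markers were higher in warm beige (also adjusted over the list alone; adjusted p = 0.209 with an estimated correlation), with a median of 3.32, Kdr, the VEGF receptor, at 3.29 ± 0.38, Cldn5 at 3.99 ± 0.42 and Egfl7 at 2.02 ± 0.17. Of 12 smooth muscle and pericyte markers 10 were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.315 with an estimated correlation), with the smooth muscle myosin gene Myh11 at 3.70 ± 0.55, Tagln at 3.62 ± 0.52 and Notch3 at 3.40 ± 0.46. Fibroblast markers were higher in 9 of 19 and lower in 3, also adjusted over the list alone (adjusted p = 0.458 with an estimated correlation). Of 3 red blood cell markers 2 were higher and 0 lower (3 and 0 adjusted over the list alone). Rn45s made up 2.06% to 2.41% of the summed values in warm white libraries, against 4.32% to 5.72% in warm beige. The skeletal muscle list had a median of 4.01 log2 units over the white mean in warm white 2 and of -0.27 or less in the other white libraries, against 2.81, 2.85 and 0.35 in warm beige.

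**Figure D3:**
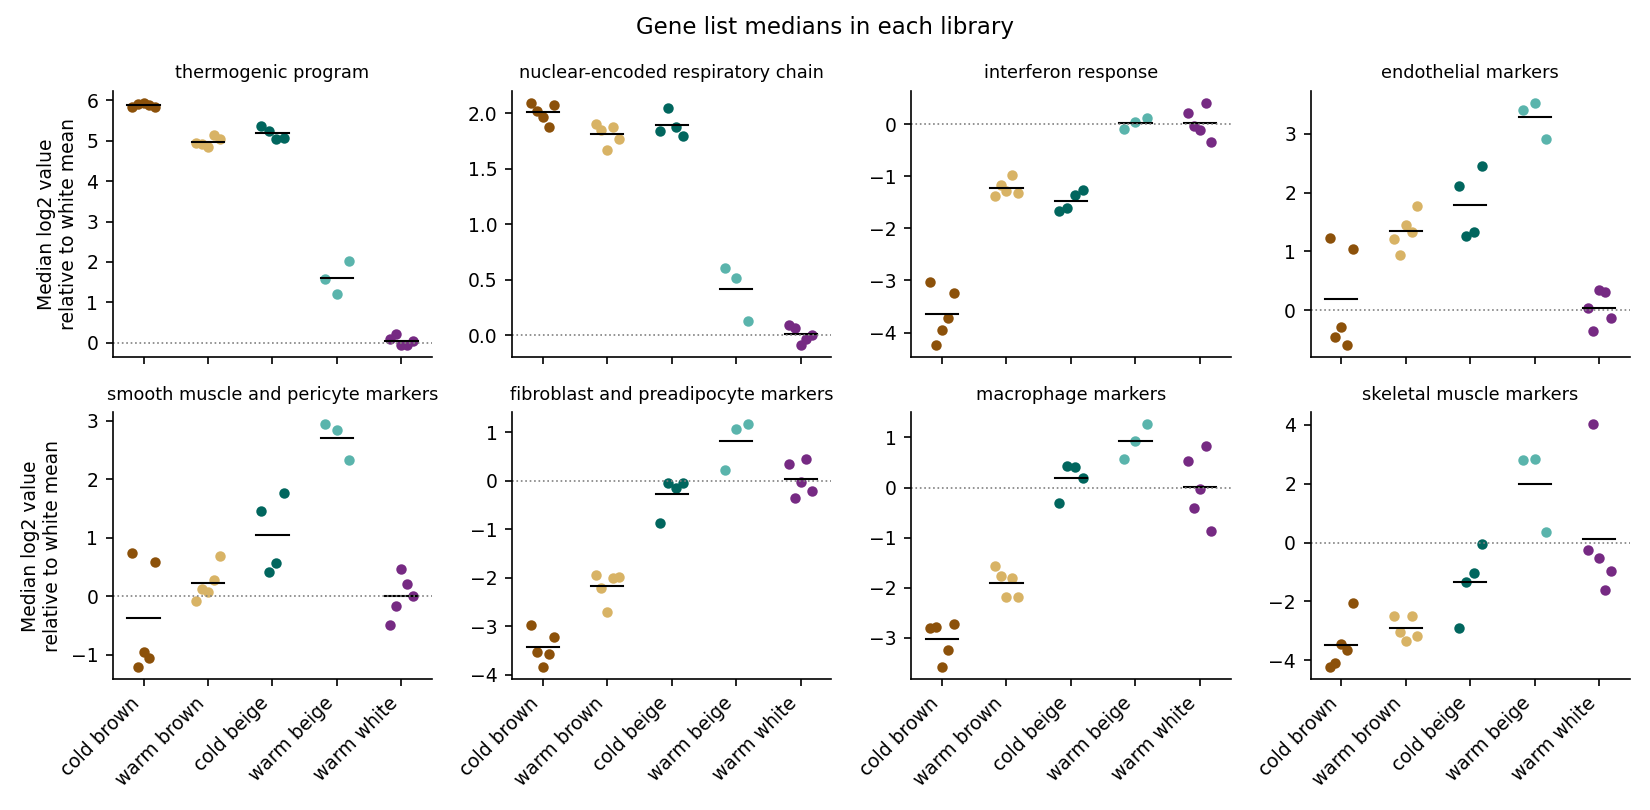
Median log2 value of 8 gene lists relative to the warm white mean (y axis) in each library of the 5 groups (x axis), with horizontal bars at group means. The endothelial median lay at 2.92 to 3.53 in warm beige and at 1.26 to 2.46 in cold beige libraries.

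Among genes with at least 10 CPM in the higher group and no overlap between the groups, the largest differences upward besides Cidea included Slc27a2, a fatty acid transporter of the thermogenic list, at 8.62 ± 0.73 (5.11 with 1 CPM added), the nuclear receptor gene Esrrg at 5.54 ± 0.70 (3.32), 8430408G22Rik at 5.04 ± 0.51 and Vwf at 4.70 ± 0.63. Nrp2, a semaphorin receptor, was higher by 4.65 ± 0.17, S100b by 4.51 ± 0.21 and Cpn2 by 4.46 ± 0.37 (2.84 with 1 CPM added). The largest downward within these limits included the cytochrome P450 gene Cyp2f2 at -4.51 ± 0.37, Agt, angiotensinogen, at -4.50 ± 0.84, Fgf13 at -4.14 ± 0.76 and the prostaglandin receptor gene Ptgfr at -4.11 ± 0.73. Others were Wfdc21 at -4.05 ± 0.64, D430019H16Rik at -3.94 ± 0.66 and Slc16a12 at -3.71 ± 0.38.

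Limma called 4572 of 11603 genes between warm beige and warm white, of which 1971 were higher and 2601 lower, and 3016 when only these groups were fitted. Within batch 2 (4 libraries) 3816 were called, with 0 in the opposite direction to the fit of all libraries. Within batch 1 (4 libraries, 1 of them warm beige) the estimates of 97.94% of the genes called in that fit had the same sign. The share of higher genes among the calls was 43.1%, and 61.0% with library totals computed without the 20 most abundant genes.

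On the axis from cold beige (0%) to warm white (100%), warm beige libraries lay at 70.7% ± 1.19 (SD, n = 3), cold beige libraries at 1.18% ± 2.17 (n = 4) and warm white libraries at 98.0% ± 3.99 (n = 5). Warm beige differed from cold beige by 69.5 percentage points (exact two-sided permutation test over 35 splits, p = 0.0286) and from warm white by -27.3 points (exact, 56 splits, p = 0.0179), both with an adjusted p of 0.0286. The batch 1 library lay at 69.3% and the 2 libraries of batch 2 at 71.3%. Of 4055 genes called with at least a 2-fold difference between the end groups, the median place in warm beige was 83.4%, with quartiles of 55.9% and 104%. Of these, 2557 lay between the ends, 1186 beyond white and 312 beyond cold beige. On the same axis cold brown libraries lay at -22.6% ± 0.678 and warm brown libraries at 16.4% ± 1.40 (n = 5 each).

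**Figure D4:**
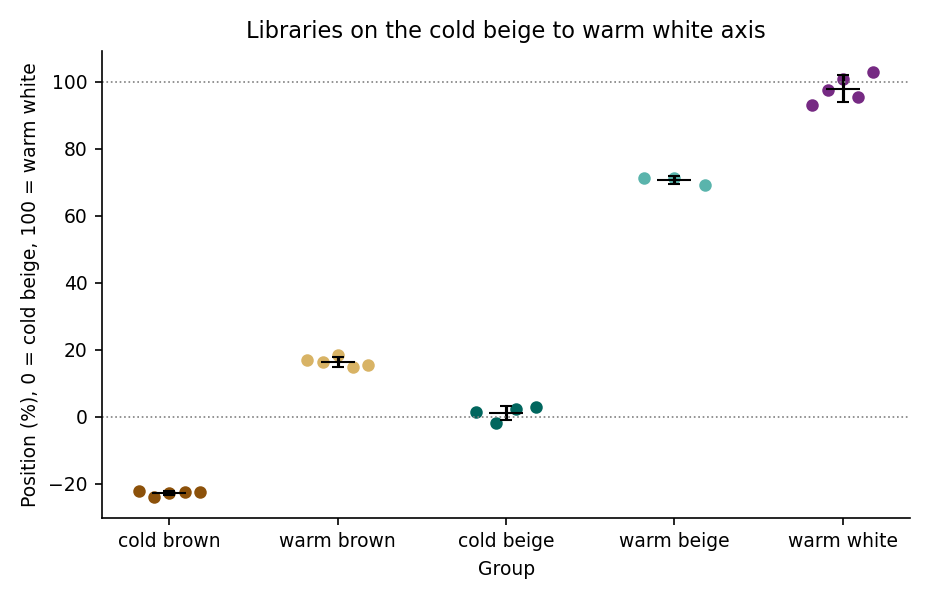
Position of each library (points) on the axis from cold beige (0%) to warm white (100%) (y axis, percent) by group (x axis), with bars at group means and standard deviations. Warm beige libraries lay at 69.3% to 71.5%, between the end groups.

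The comparison of cold beige with warm white libraries gives the ends of that axis, with lifelong temperature and possibly mouse line differing too (n = 4 and 5). Ucp1 was higher in cold beige by 14.16 ± 0.52 log2 units (11.07 with 1 CPM added; adjusted p = 1.37e-16), Elovl3 by 14.08 ± 0.52 (8.78), Dio2 by 11.13 ± 0.66 (8.89), Cidea by 7.57 ± 0.27 and Ppargc1a by 2.79 ± 0.13. Lep was lower by 4.37 ± 0.35 and Adipoq was lower by 1.56 ± 0.15. All 29 thermogenic members were higher, also adjusted over the list alone (camera, adjusted p = 0.000308), with a median of 5.18, Cox8b at 6.67 ± 0.11, Gk at 6.44 ± 0.12 and Letmd1 at 4.65 ± 0.07. In the respiratory chain 75 of 76 were higher and 1 lower, also adjusted over the list alone (adjusted p = 0.158 with an estimated correlation). White markers were lower in 16 of 17 and higher in 1, also adjusted over the list alone (adjusted p = 0.156 with an estimated correlation), with Ccdc80 at -4.58 ± 0.18 and Nnat at -5.96 ± 0.32. The endothelial list was higher in 18 of 18, also adjusted over the list alone (adjusted p = 0.718 with an estimated correlation). Smooth muscle and pericyte markers were higher in 7 of 12 and lower in 1, also adjusted over the list alone (adjusted p = 0.817 with an estimated correlation). All 3 measured red blood cell markers were higher, with a median of 3.60. Rn45s made up 0.436% to 1.15% of the summed values in cold beige and 2.06% to 2.41% in warm white libraries.

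Among the largest differences, Lgr6 was higher in cold beige by 12.13 ± 0.71 (6.93 with 1 CPM added), the thioesterase gene Acot11 by 11.86 ± 0.46 (9.79) and Kng2 by 11.65 ± 0.75 (6.56). Cyp2b10 stood at 5.93 ± 0.68 log2 CPM in cold beige and at the floor in every white library. The protease gene Prtn3 was lower by 6.91 ± 0.52, Agt by a change of -6.04 ± 0.77 and Emp1 by a change of -6.0 ± 0.36. Limma called 8731 genes, 4414 higher and 4317 lower, with 6996 in batch 1 and 7801 in batch 2. Within the batches 0 were called in the opposite direction to the fit of all libraries. The share of higher genes among the calls was 50.6%, and 44.4% with library totals computed without the 20 most abundant genes.

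The comparison of cold beige with cold brown libraries sets the activated cells of both depots side by side, with cell type and depot changing together (n = 4 and 5). None of the thermogenic fixed genes passed: Ucp1 differed by -0.81 ± 0.52 (adjusted p = 0.183), Elovl3 by -0.52 ± 0.52 (0.405), Dio2 by -0.42 ± 0.66 (0.6), Cidea by -0.35 ± 0.27 (0.26) and Ppargc1a by -0.09 ± 0.13 (0.57). When only these groups were fitted Ucp1 (adjusted p = 0.000674), Elovl3 (0.000936), Cidea (0.000922) and Dio2 (0.0465) passed. With temperature and library number together as a block Ucp1 (0.0152) and Dio2 (0.0317) passed. With 0.25, 1 or 5 CPM added Ucp1 (0.00395, 0.000258 and 4.91e-05) and Elovl3 (0.00412, 0.000112 and 1.06e-05) passed, as did Ucp1 after quantile normalization (0.0121) and Dio2 with 5 CPM added (0.0366). The sign of Ppargc1a turned to 0.01 without cold brown 3. Lep was higher in cold beige by 4.46 ± 0.35, and Adipoq was lower by 0.80 ± 0.15.

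The reported beige markers were higher in cold beige (camera, adjusted p = 0.0049), with 8 of 9 members higher and 0 lower, also adjusted over the list alone, and a median of 2.95. With temperature and library number together as a block the list's adjusted p was 0.242. Tbx1, a T-box factor, was higher by 7.99 ± 0.75 (3.29 with 1 CPM added), the homeobox gene Shox2 by 5.33 ± 0.28 and the fatty acid transporter gene Slc27a1 by 1.74 ± 0.08. HOX genes, which mark body position, were higher in 13 of 20 and lower in 5, also adjusted over the list alone (adjusted p = 0.339 with an estimated correlation). Hoxc10 at 4.70 ± 0.16, Hoxa10 at 4.50 ± 0.19 and Hoxc9 at 3.23 ± 0.20 log2 CPM in cold beige were at the floor in every cold brown library. Zic1, a marker of classical brown fat, stood at 4.14 ± 0.20 log2 CPM in cold brown and at the floor in every cold beige library. Thermogenic members were lower in 11 of 29 and higher in 3 (9 and 3 adjusted over the list alone; adjusted p = 0.222 with an estimated correlation). Against warm white, of the same depot, the reported beige markers counted 3 of 9 higher in cold beige and 3 lower (camera, adjusted p = 0.936).

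White markers were higher in cold beige than in cold brown in 14 of 17 and lower in 0, also adjusted over the list alone (adjusted p = 0.0877 with an estimated correlation), with Retn, resistin, at 6.41 ± 0.27 and Ccdc80 at 3.10 ± 0.18. All 12 macrophage markers were higher, also adjusted over the list alone (adjusted p = 0.194 with an estimated correlation), with the scavenger receptor genes Cd163 at 3.82 ± 0.23 and Mrc1 at 3.21 ± 0.26. Fibroblast markers were higher in 18 of 19 and lower in 1, also adjusted over the list alone (adjusted p = 0.185 with an estimated correlation), with Gsn at 4.44 ± 0.17 and Col3a1 at 4.30 ± 0.24. Endothelial markers were higher in 14 of 18 and lower in 0 (16 and 0 adjusted over the list alone; adjusted p = 0.622 with an estimated correlation). Rn45s made up 0.436% to 1.15% of the summed values in cold beige and 0.058% to 0.099% in cold brown libraries. Among the largest other differences were Snhg11 at 7.41 ± 0.53 (3.88 with 1 CPM added), Fgf10 at 6.87 ± 0.41, the short-chain fatty acid receptor gene Ffar2 at 6.80 ± 0.36 (4.46) and the complement gene C4b at 6.68 ± 0.22. Downward lay Ankrd33b at -5.14 ± 0.38, the ketone enzyme gene Bdh1 at -4.92 ± 0.59 and the nucleoside transporter gene Slc29a1 at -3.66 ± 0.23. Limma called 7184 genes, 4024 higher and 3160 lower, with 3710 in batch 1 and 6034 in batch 2. Within the batches 0 were called in the opposite direction to the fit of all libraries. The share of higher genes among the calls was 56.0%, and it was 45.8% after median-of-ratios scaling and 46.0% after quantile normalization.

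The comparison of warm beige with warm brown libraries repeats this after rewarming (n = 3 and 5). Ucp1 was lower in warm beige by a change of -7.82 ± 0.57 log2 units (adjusted p = 3.88e-11), Dio2 differed by -3.72 ± 0.72, Cidea by -2.47 ± 0.29, Ppargc1a by -1.37 ± 0.14 and Elovl3 by -4.36 ± 0.57 (-0.74 with 1 CPM added, and no longer past the test with 5, adjusted p = 0.0523). Lep was higher by 1.51 ± 0.38, and Adipoq, at -0.29 ± 0.16, did not pass (adjusted p = 0.0991). The thermogenic list was lower in warm beige (camera, adjusted p = 0.00525), with 27 of 29 members lower and 0 higher, also adjusted over the list alone, and a median of -3.03. Clstn3 differed by -3.97 ± 0.12, Cox8b by -3.72 ± 0.13 and Letmd1 by -3.03 ± 0.08. The reported beige markers were higher (camera, adjusted p = 0.036), with 8 of 9 higher and 1 lower, also adjusted over the list alone, with Shox2 at 5.80 ± 0.31 and Slc27a1 at 0.91 ± 0.08. With temperature and library number together as a block both lists had an adjusted p of 0.357, with library number alone 0.0106 and 0.059, and with replicate number 0.0125 and 0.0537. Against warm white, of the same depot, the reported beige markers counted 1 of 9 higher in warm beige and 2 lower (camera, adjusted p = 0.766).

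In the respiratory chain 68 of 76 genes were lower in warm beige and 2 higher (70 and 2 adjusted over the list alone; adjusted p = 0.227 with an estimated correlation). Skeletal muscle markers were higher in 14 of 16 and lower in 2, also adjusted over the list alone (adjusted p = 0.601 with an estimated correlation), with a median of 6.21, and fibroblast markers were higher in 18 of 19 and lower in 1, also adjusted over the list alone (adjusted p = 0.188 with an estimated correlation). Macrophage markers were higher in 11 of 12 and lower in 0 (adjusted p = 0.227 with an estimated correlation), endothelial markers in 14 of 18 and lower in 0 (adjusted p = 0.542 with an estimated correlation), and smooth muscle and pericyte markers in 9 of 12 and lower in 1 (adjusted p = 0.585 with an estimated correlation), each also adjusted over the list alone. Rn45s made up 4.32% to 5.72% of the summed values in warm beige and 0.11% to 0.597% in warm brown libraries. Hoxa10 at 4.61 ± 0.13, Hoxc10 at 4.20 ± 0.20 and Hoxc9 at 3.68 ± 0.20 log2 CPM in warm beige were at the floor in every warm brown library. Lgr6 differed by -11.29 ± 0.77 (-6.95 with 1 CPM added), Kng2 by -9.93 ± 0.81 (-7.07) and Arhgdig by -9.77 ± 0.51 (-5.13), and A530050N04Rik was at the floor in every warm beige library. Limma called 8758 genes, 4100 higher and 4658 lower, with 8326 in batch 2. Within batch 2, 0 were called in the opposite direction to the fit of all libraries. Within batch 1, which holds 1 warm beige library, the estimates of 99.03% of the genes called in that fit had the same sign. The share of higher genes among the calls was 46.8%, and 54.6% with library totals computed without the 20 most abundant genes.

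The comparison of warm brown with warm white libraries shows how far brown cells stood from white cells at 30 °C (n = 5 each). Depot and lifelong temperature differed too, and the mouse line may have differed. Ucp1 was higher in warm brown by 11.66 ± 0.49 log2 units (8.58 with 1 CPM added; adjusted p = 1.09e-15), Dio2 by 7.47 ± 0.62, Cidea by 7.23 ± 0.25, Elovl3 by 4.88 ± 0.49 (0.77) and Ppargc1a by 2.20 ± 0.12. Lep was lower by 2.57 ± 0.33 and Adipoq was lower by 0.51 ± 0.14. The thermogenic list was higher (camera, adjusted p = 0.00133), with 28 of 29 members higher and 1 lower, also adjusted over the list alone, and a median of 4.91, with Cpt1b at 9.21 ± 0.19 and Letmd1 at 3.67 ± 0.07. The reported beige markers were lower (camera, adjusted p = 0.0497), with 8 of 9 lower and 1 higher, also adjusted over the list alone, with Shox2 at -5.93 ± 0.27 and Slc27a1 at -1.32 ± 0.07, and a call that was lost with a batch term (0.053) or a block of replicate (0.0738) or library number (0.0759). Fibroblast markers were lower in 15 of 19 and higher in 1, also adjusted over the list alone (adjusted p = 0.375 with an estimated correlation). Macrophage markers were lower in 11 of 12 and higher in 0, also adjusted over the list alone (adjusted p = 0.391 with an estimated correlation). Skeletal muscle markers were lower in 11 of 16 and higher in 2, also adjusted over the list alone (adjusted p = 0.857 with an estimated correlation). Endothelial markers were higher in 12 of 18 and lower in 1, also adjusted over the list alone (adjusted p = 0.857 with an estimated correlation). Rn45s made up 0.11% to 0.597% of the summed values in warm brown and 2.06% to 2.41% in warm white libraries.

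Among the largest differences, Kng2 was higher in warm brown by 12.50 ± 0.71 (7.41 with 1 CPM added), Lgr6 by 12.35 ± 0.67 (7.15) and Slc27a2 by 11.83 ± 0.63 (8.29). Wfdc21 differed by -10.48 ± 0.56 (-5.81), the protease inhibitor gene Serpina3n by -9.71 ± 0.59 (-7.84), and Hoxa10 and Hoxc9 were at the floor in every warm brown library, against 5.17 ± 0.26 and 4.39 ± 0.24 log2 CPM in white. Limma called 9161 genes, 4742 higher and 4419 lower, with 7230 in batch 1 and 8368 in batch 2. Within the batches 0 were called in the opposite direction to the fit of all libraries. The share of higher genes among the calls was 51.8%, and it was 48.9% after quantile normalization and 49.1% with library totals computed without the 20 most abundant genes.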

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

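The tests of a lower share of labelled cells, of a factor common to all genes and of mixing, and the splits that follow the pairs, were chosen only after their results were seen, adding 1 CPM, the planned scale, became an alternative once the data were seen to be logarithms, and the remaining tests in this part were written before.

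Effects of warming that differed between cell types stood out by the test of the difference itself, with 5477 genes and 24 of the 29 measured thermogenic members called lower. The log2 differences, beige minus brown, of the fixed genes were -7.0033 for Ucp1, -2.1192 for Cidea, -1.2857 for Ppargc1a, -3.8425 for Elovl3 (-0.229 with 1 CPM added), -3.3002 for Dio2 and -2.9463 for Lep. Upward lay, with the value with 1 CPM added in brackets, Pvalb at 7.3425 (3.1085), Acta1 at 6.6375 (3.2245), A930016O22Rik at 6.3213 (3.5), Myh4 at 6.2898 (4.2256), Tnni2 at 5.625 (2.5897), Sult5a1 at 4.2303 (2.3086) and Hopx at 4.079 (3.425). Downward lay Lgr6 at -10.545 (-6.2154), A530050N04Rik at -9.0378 (-3.2545), Arhgdig at -8.5885 (-3.9984), Kng2 at -8.3707 (-5.5127), Cdsn at -7.0723 (-3.3217), Cfap54 at -7.0457 (-3.885) and Sgk2 at -6.4478 (-0.9665), so these sizes depend on values near the floor, where A530050N04Rik and Sgk2 lay in every warm beige library. Among list members the values were -2.5635 for Letmd1, -3.7233 for Cox8b, -3.5852 for Clstn3, -3.5867 for Ppara, -1.8482 for Ndufa8, -2.4677 for Cycs, -2.5178 for Slc25a20 and -2.9212 for Acaa2.

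Single libraries stood apart from their group in 3 of 76 groups over 19 measures, where chance gives about 5%. The warm beige group was too small for the rule and was not checked. Elovl3 lay at -2.99 log2 CPM in warm white 4, against -5.73 in the nearest library. The median of the fibroblast markers relative to the white mean lay at -0.876 in cold beige 1, against -0.138 in the nearest. The median of the skeletal muscle markers lay at 4.011 in warm white 2, against -0.271 in the nearest. The named genes other than the fixed ones were not put to this check. In the unchecked warm beige group the skeletal muscle medians were 2.811, 2.846 and 0.352. Elovl3 lay there at -5.73, -5.73 and -2.73 log2 CPM.

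Other splits of the same libraries into groups of the same sizes were fitted in the same way. For beige warming 1 of 35 splits, the real one, gave as many genes as the real 8453 (highest other 6781), and for warm beige against warm white it was 1 of 56, with 4572 and 1183. For warm beige against warm brown it was 1 of 56 (8758 and 5226), and 1 of 100 drawn for brown warming (8274 and 4024), cold beige against warm white (8731 and 7788), cold beige against cold brown (7184 and 5616) and warm brown against warm white (9161 and 6051). Chance is excluded at 0.05 in each of these if the libraries are exchangeable. Where same-numbered beige and brown libraries are taken as pairs, only 16 splits (cold) and 8 splits (warm) part every pair, too few for a share under 0.05, with highest others of 5020 against 7184 and 2724 against 8758. For the difference of warming effects 4 of 100 splits drawn gave at least the real 5477, a share under 0.05, with a highest other of 8452. That split left 1 of 7 beige libraries in its own group, with the 10 brown libraries in place or all swapped, so it follows the temperature of the samples. The other splits that passed the real count called 5986 and 5964, and the latter left all 7 beige libraries in place. Of 100 splits drawn from the 105 that keep every pair on one side, 1, the real one, gave as many, with a highest other of 3586. Both sets of splits exchange temperatures within each cell type, so they set the data against no warming effect in either. Equal effects in both cell types were not simulated by them, and they cannot decide whether the effects differed.

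Markers of other cell types in warm beige libraries form a pattern in which 18 of 18 endothelial markers were higher than in warm white. A lower share of RNA from the labelled cells raises the markers of every other type alike. From warm white to warm beige the medians of the endothelial, mural, fibroblast and macrophage lists lay 2.486 log2 units apart. Shuffling genes among the lists gave a permutation p of 0.0045. Genes of a list move together (estimated correlations of 0.304 to 0.777), so this p does not measure the spread between libraries. In warm beige libraries the endothelial medians relative to the white mean were 2.92 to 3.53. The fibroblast medians were 0.22 to 1.16 and the macrophage medians 0.58 to 1.26. The distance argues against that explanation as the whole cause, if the mix of other cells was the same in these groups. The endothelial median lay 3.358 above that of all genes (lower quartile 2.992, against an upper quartile of 0.253 for all genes). That argues against a factor common to all genes of a library. The endothelial median of 3.332 after median-of-ratios scaling decides nothing because that scaling moved the median gene by only 0.014. From cold to warm beige the medians of the same lists all rose and lay 0.762 apart (same permutation, p = 0.218), which does not show that they moved alike. The skeletal muscle list rose by a median of 4.159, while the 3 red blood cell markers had a median of -1.686, with 1 called lower. These values left a lower share from cold to warm beige undecided. A change in the vascular cells themselves stays open as an untested biological explanation. The labels do not give the mouse line of each library, so a difference of line between warm beige and warm white could not be checked.

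Unequal retention of cold beige transcripts in warm beige libraries is the next pattern, with retained shares of the difference from white of 0.0731% for Ucp1, 0.554% for Dio2, 13.8% for Cidea, 41.5% for Pdk4 and 83% for Nrp2, and a median of 5.15%. Unchanged beige transcripts mixed with white adipocyte RNA would give every gene the same share, yet at the best share, 4%, 54.59% of 621 genes lay outside their interval, where 5% is nominal. That argues against mixing as the whole cause for these genes. The margin was narrow, since the bound was 50% and the range without any 1 library was 50.24% to 56.68%. Markers of other cell types were not removed from the 621 genes. All 18 endothelial markers were higher in cold beige than in warm white and 13 of 18 rose further on warming, which no mixing share gives. How many of them were among the 621 was not counted, so the test does not decide for beige transcripts alone. The reading of this bound was changed after the values were seen, from the value alone to an interval and then to the leave-one-out range, and the verdict on these 621 genes was the same under each. Among 185 genes of at least 50 CPM, 52.97% lay outside (48.11% to 55.68%), and the change of reading moved unequal noise of low genes from excluded to one that cannot be told apart, since this range crosses the bound, and unequal loss from gene to gene stays an untested biological explanation.

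Thermogenic genes higher in warm beige than in warm white libraries numbered 20. With the mean of the skeletal muscle markers in each library as a covariate 19 of these were still called higher, their median going from 3.743 to 3.06, which argues against muscle RNA as the whole cause. With 5 CPM added to every value 20 were still called, with a median of 0.98. Adding CPM keeps the order of libraries, so this cannot decide on a constant added to low values. With the endothelial mean as covariate 14 were still called, with a median of 3.012 and a median SE that went from 0.262 to 0.521, and the calls over all genes went from 4572 to 1032. Endothelial RNA therefore cannot be told apart from the groups, which its markers separate in full. Their medians relative to the white mean were 2.92 to 3.53 in warm beige and -0.36 to 0.35 in warm white. Past cold exposure of the beige cells stays open as an untested biological explanation, and it cannot be told apart from a possible difference of mouse line.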

How the results depend on the processing

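Chosen only after the data were seen were the tests within each batch, with a batch term and with temperature and library number together as a block, and for the position those with 5 CPM added, with median-of-ratios scaling and without other cells' lists. Adding 1 CPM was the planned scale and became an alternative once the data were seen to be logarithms. Over the settings other than single batches the count of genes was 7870 to 8660 for beige warming (8453), 7595 to 9038 for brown warming (8274), 5237 to 6237 for the difference of warming effects (5477), 3016 to 5036 for warm beige against warm white (4572), 8437 to 8924 for cold beige against warm white (8731), 6771 to 8111 for cold beige against cold brown (7184), 8354 to 8918 for warm beige against warm brown (8758) and 8771 to 9337 for warm brown against warm white (9161). Leaving out each library in turn gave 7941 to 8245, 7953 to 8172, 5057 to 5455, 3830 to 4433, 8439 to 8639, 6607 to 6966, 8332 to 8653 and 8893 to 9068 in the same order. Fitting only the compared groups gave 3016 in place of 4572 for warm beige against warm white. Batch 1 alone, which holds fewer libraries, gave 5255 for beige warming, 5050 for brown warming, 1969 for the difference, 1304 for warm beige against warm white and 3710 for cold beige against cold brown.

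Of 240 list tests 9 passed with an estimated correlation, 100 with the preset correlation and 182 with fry, which does not compare a list with other genes. With the replicate number as a block 10 passed and the counts of genes were 8352, 8267, 5331, 4214, 8655, 7080, 8675 and 9144 in the order above, and with the library number as a block 7 passed. Both blocks ended the call of the reported beige markers in warm beige against warm brown (0.0537 and 0.059) and in warm brown against warm white (0.0738 and 0.0759), the latter also lost with a batch term (0.053). The replicate number added fatty acid oxidation (0.0228) and peroxisome (0.0419) in beige warming and fatty acid oxidation in cold beige against warm white (0.0152). With temperature and library number together as a block, 0 in place of 4 list calls passed in the 3 comparisons of beige with brown, with 5294, 7065 and 8543 genes called. Among named genes a block ended the calls of Tnni2 (adjusted p = 0.0599 with the replicate number, 0.0727 with the library number) and A930016O22Rik (0.0504, library number) in the difference of warming effects, and of Lep in warm beige against warm white (0.0599, library number). With temperature and library number together Ucp1 (0.0152) and Dio2 (0.0317) passed in cold beige against cold brown. The blocks changed no other call of a named gene in the comparisons they were run on, and no count of genes moved by over 1.5 times. The cause was not tested.

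The position of warm beige, 70.651%, was 73.427% with 0.25 CPM added, 75.759% with 1 and 79.314% with 5. It was 77.902% after quantile normalization, 87.658% as the median over genes, 67.234% in batch 1 and 72.882% in batch 2. It was 70.59% after median-of-ratios scaling and 71.08% without the lists of other cell types. Leaving out any 1 warm beige library gave 70.247% to 71.437%, and no cold beige or warm white library was left out. Adding CPM shrinks genes near the floor, and the cause of the other moves was not tested.

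Elovl3 turned to 0.3199 and Sgk2 to 0.2973 in the difference of warming effects with 5 CPM added, where values at the floor shrink. Elovl3 in warm beige against warm white (0.52, not past the test) turned to -0.1868 after quantile normalization and -0.2655 with library weights, and ran from -0.482 (without warm beige 3) to 1.0825 (without warm white 4). Ppargc1a in cold beige against cold brown ran from -0.15 (without cold brown 4) to 0.0075 (without cold brown 3). Coro1a in beige warming, not past the test, ran from -0.1775 (without warm beige 3) to 0.8175 (without warm beige 1). The cause of these was not tested. Of 6745 values of 275 named genes and comparisons under the alternatives, 6672 stayed on the same side of the threshold with the same sign, 33 lost a call, 33 gained one and 7 turned sign.

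Rescaling moved the median log2 fold change by 0.152 in beige and brown warming when libraries were set to a common total. Median-of-ratios scaling moved it by -0.114 in brown warming, 0.153 in the difference and -0.104 in cold beige against cold brown, and quantile normalization by -0.14 in brown warming and 0.205 in the difference. Totals without the 20 most abundant genes moved it by 0.222 and 0.127 in beige and brown warming, 0.102 in warm beige against warm white, -0.12 in cold beige against warm white and 0.154 in warm beige against warm brown. Fits of counts by edgeR and DESeq2, a sex term and a batch term from the labels were not run, because no counts could be recovered, a single sex occurred and no batch is named in the table. No filter in place of the main one moved nothing. Depth is unknown, so low genes had no limit of detection other than the floor.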

Other observations

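Adding 1 CPM, the planned scale, became an alternative only after the data were seen to be logarithms, no other test in this part was chosen after its result was seen, and which lists and members to describe was chosen after. In beige cells on warming, further metabolic genes fell. Of 28 peroxisomal genes 23 fell and 4 rose, also adjusted over the list alone (adjusted p = 0.121 with an estimated correlation), with the transporter gene Abcd3 at -2.93 ± 0.12 and Pex14 at -1.98 ± 0.09. Of 21 genes of branched-chain amino acid catabolism 16 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.238 with an estimated correlation), with Dld at -1.94 ± 0.09 and Bckdha at -1.60 ± 0.08. Of 22 cholesterol genes 17 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.352 with an estimated correlation), with Hmgcs1 at -2.32 ± 0.14 and Dhcr7 at -1.90 ± 0.11. Of 16 genes of the amino acid response 10 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.543 with an estimated correlation), with Psph, a serine synthesis enzyme, at -1.64 ± 0.12. In brown cells the same list held Phgdh, which makes serine, at 4.53 ± 0.31 and the transporter gene Slc3a2 at -1.51 ± 0.09.

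Lipolysis genes fell in 9 of 19 and rose in 4, also adjusted over the list alone (adjusted p = 0.49 with an estimated correlation), with Prkaca, a catalytic subunit of protein kinase A, at -1.97 ± 0.07. Creatine and calcium cycling genes fell in 5 of 9 and rose in 3, also adjusted over the list alone (adjusted p = 0.686 with an estimated correlation), a direction that turned under another scaling, with the creatine kinase gene Ckb at -2.74 ± 0.22 and the calcium pump gene Atp2a2 at -1.58 ± 0.10. Matrix genes rose in 15 of 26 and fell in 1, also adjusted over the list alone (adjusted p = 0.352 with an estimated correlation), with the collagen gene Col5a2 at 2.20 ± 0.21 and the laminin gene Lamc1 at 1.09 ± 0.09. Genes of insulin and adipokine signalling rose in 11 of 25 and fell in 6, also adjusted over the list alone (adjusted p = 0.49 with an estimated correlation), and their median (0.335) and test were positive while their mean was -0.05. Among these the receptor gene Igf1r stood at 1.95 ± 0.12 and Foxo3 at 1.69 ± 0.15, and the glucose transporter gene Slc2a4 at -1.76 ± 0.09.

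Clock genes fell in 6 of 14 and rose in 5, also adjusted over the list alone (adjusted p = 0.881 with an estimated correlation), a direction that turned under another scaling, with Nfil3 at -2.34 ± 0.19, Clock at -1.13 ± 0.10 and Nr1d1 at 0.59 ± 0.07. Immediate early genes rose in 11 of 20 and fell in 5 (12 and 5 adjusted over the list alone; adjusted p = 0.543 with an estimated correlation), with Klf6 at 2.55 ± 0.25 and Fosl2 at 1.91 ± 0.14. Ribosomal protein genes rose in 37 of 73 and fell in 18, also adjusted over the list alone (adjusted p = 0.683 with an estimated correlation), with Rpl7l1 at -1.15 ± 0.09. Cell cycle genes rose in 6 of 12 and fell in 2, also adjusted over the list alone (adjusted p = 0.543 with an estimated correlation), with the helicase gene Mcm4 at 2.20 ± 0.16.

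Of lineage lists, HOX genes rose in 8 of 20 and fell in 2 (6 and 2 adjusted over the list alone; adjusted p = 0.543 with an estimated correlation), with Hoxa4 at -2.63 ± 0.33. Classical brown markers rose in 2 of 7 and fell in 2, also adjusted over the list alone (adjusted p = 0.881 with an estimated correlation), a direction that turned under another scaling, with Mpzl2 at -2.55 ± 0.21 and Lhx8 at 2.0 ± 0.20. Reported beige markers rose in 3 of 9 and fell in 3, also adjusted over the list alone (adjusted p = 0.995 with an estimated correlation), a direction that turned under another scaling, and their median (0.455) and test were positive while their mean was -0.04. Pan-adipocyte markers rose in 6 of 18 and fell in 7, also adjusted over the list alone (adjusted p = 0.995 with an estimated correlation), a direction that turned under another scaling, and their median (-0.07) and test were negative while their mean was 0.045, with the lipid droplet gene Plin4 at 1.67 ± 0.11.

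Macrophage markers rose in 6 of 12 and fell in 0 (3 and 0 adjusted over the list alone; adjusted p = 0.661 with an estimated correlation), with Cd14 at 3.35 ± 0.31. Smooth muscle and pericyte markers rose in 7 of 12 and fell in 2, also adjusted over the list alone (adjusted p = 0.69 with an estimated correlation), with Myh11 at 2.75 ± 0.57. Nerve and Schwann cell markers rose in 3 of 6 and fell in 2, also adjusted over the list alone (adjusted p = 0.814 with an estimated correlation), with S100b at -3.78 ± 0.22 and Cnp, a myelin gene, at 1.57 ± 0.19. Of 4 genes of the Y-linked and Xist list 1 fell, also adjusted over the list alone (adjusted p = 0.69 with an estimated correlation), a direction that turned under another scaling, and this was Uty at -0.75 ± 0.09.

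Lists with fewer than 4 measured genes were not tested. The mammary list held Trf at 2.55 ± 0.31, which passed the test of single genes, and the lymphocyte list held Coro1a at 0.22 ± 0.56 (adjusted p = 0.736), whose sign turned without warm beige 3 (-0.18). The red blood cell list held Hbb-bs at -1.75 ± 0.37 (adjusted p = 0.000252), Hba-a2 at -1.69 ± 0.77 (-0.85 with 1 CPM added; adjusted p = 0.0541, but past the test without warm beige 3 (0.0242), with 0.25, 1 or 5 CPM added (0.00669, 0.00732 and 0.0245), after quantile normalization (0.00253), with library weights (0.00187) and when only these groups were fitted (0.0287)) and Alas2 at -0.47 ± 0.37 (adjusted p = 0.253). The list of mitochondrially encoded genes had no measured gene.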
